A study of Mus musculus with 12 samples.

How the data were processed

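Gene expression was measured in RAW 264.7 cells, an adherent mouse monocyte/macrophage line transformed by Abelson murine leukaemia virus. Cells were collected 48 h after transfection with an irrelevant scramble oligonucleotide, with pre-miR-223, a mimic that adds miR-223 activity, or with anti-miR-223, an inhibitor that binds miR-223. Each of the 3 groups had 4 arrays titled as biological replicates, 12 arrays in total. Per the labels, total RNA came from a miRNeasy extraction, its quality was checked on a Bioanalyzer, and it was labelled with the WT PLUS reagents for Affymetrix whole-transcript arrays.

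The authors deposited 1 table of 41345 transcript clusters for the 12 arrays, in log2 units and already normalised between arrays. The submitters' processing notes name Affymetrix Expression Console, RMA and Partek, with no version and no statement of what each did. RMA subtracts background, equalises the arrays' distributions and summarises probes on a log2 scale, so differences in total RNA output between groups cannot be seen in such values. The base of the logarithm is not stated and was taken as 2, because RMA gives log2 values and the deposited values lay between 0.53 and 12.45. No genome build is stated, so no coordinates are given.

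A table pairing clusters with genes annotated 25335 clusters, of which 23521 had a single gene symbol and 1814 had several; the other 16010 were unnamed. Only clusters with a single symbol were used. They covered 22180 symbols, 1082 of them with more than 1 cluster, and the cluster with the highest mean over the 12 arrays was taken for each symbol. Genes were tested if that mean lay above the 40th percentile of all clusters, log2 2.01, which left 14611 genes. Of these, 14516 matched a RefSeq gene table (GRCm38.p6) by identifier and 95 did not; that table was used only for gene types and gene spans. No cluster had Mir223 as its only symbol, so the delivery of the mimic or the inhibitor was not checked here.

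Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend or robust options), with 1 model for all 12 arrays, 9 residual degrees of freedom and no covariates. The 3 contrasts were pre-miR-223 against scramble, anti-miR-223 against scramble and pre-miR-223 against anti-miR-223. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over the 14611 genes, 2-sided. Changes are log2 differences of group means with 95% confidence intervals from the same model; group means are given with their SD, n = 4 arrays. Arrays give no count depth, and their number limits the precision.

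Lists of genes were fixed before the data were examined: 24 lists with 474 distinct genes, of which 387 were tested, 46 had no cluster with a single symbol and 41 lay below the level required. They covered reported miR-223 targets, cholesterol synthesis, LXR-driven efflux and lipogenesis, NF-kB driven inflammation, chemokines, the interferon response, alternative activation, macrophage identity, osteoclast genes, G1/S replication, G2/M mitosis, p53 targets, the unfolded protein and integrated stress response, the NRF2 oxidative response, glycolysis and hypoxia, the microRNA machinery, PI3K, FOXO and IGF signalling, lysosome, ribosomal proteins, and markers of fibroblasts, epithelium, lymphoid cells, and neutrophils or dendritic cells. The result of 1 further list is not reported here. Each list was tested against all other genes with camera at a preset correlation of 0.01, with adjustment over the 24 lists. Camera with an estimated correlation and fry stood beside it. A level-matched score per array was added after the data were seen: the mean of a list minus the mean of other genes of the same level in 50 level bins. It was compared by a 2-sided exact permutation test over the 70 labelled splits of 4 against 4 arrays, whose smallest p is 0.0286. The same test was applied to the median deviation of protein-coding genes above log2 5 with a short gene span (at most 9.14 kb, 947 genes) or a long one (at least 64.6 kb, 947 genes). Matching on level and gene span together, in 10 by 10 bins, was also added later.

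The genes named were set by a rule written before the data were examined. With no gene called, it took the 5 genes with the smallest p in each comparison, apart from predicted, olfactory, vomeronasal and small RNA genes. It also took the member with the smallest p of the lists for miR-223 targets, cholesterol synthesis, NF-kB inflammation, interferon response and osteoclast genes. Mef2c, Nlrp3, Nfia, Lmo2, Rhob, Stmn1 and E2f1 were named in every comparison; Mir223 and Igf1r were on that list too but were not among the genes tested. This gave 29 genes. Other genes are named as examples and were chosen after their values were seen.

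The procedure was tested on simulated data made from the residuals of the 12 arrays turned by random rotations, 10 draws with 50 changed genes per fold size among 14611. For pre-miR-223 against scramble, 51.2% of genes with a 1.5-fold change, 84.2% with 2-fold and 98.8% with 3-fold were recovered. The shares were 39.4%, 77.6% and 97.0% for anti-miR-223 against scramble and 42.8%, 82.8% and 98.6% for pre-miR-223 against anti-miR-223. The median number of unchanged genes called was 9, 0 and 1, in this order of comparisons. Genes with 4-fold changes were planted in the same draws, and larger changes ease the adjusted threshold for smaller ones. The shares therefore do not apply to data with few changed genes. A shift of -0.30 planted in the 29 tested miR-223 targets was called in 10 of 10 draws in each comparison with the preset correlation. The estimated correlation called it in 6, 4 and 3 draws, in the same order. With the preset correlation, other lists that had not been changed were called in numbers of up to 9, 14 and 8 in a draw. The rotations treat the 3 comparisons alike, so differences between them in these shares and counts reflect the random draws. They also spread the deviation of any single array over all 12 arrays, unlike in the real data.

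The alternatives varied the level filter, the unit tested, the choice of cluster, the scaling between arrays, the variance moderation, array weights, the arrays in the fit, the replicate number as a block, the threshold, and each array left out in turn. Alternatives added after the data were seen were cyclic loess, residual principal components as covariates, median centring for the lists, the level-matched scores and further left-out arrays. A planned comparison of genes with and without miR-223 seed matches in their 3' UTRs was not run, since no UTR sequences were used here. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.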

Results

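RAW 264.7 cells were profiled to ask which transcripts follow a gain or a loss of miR-223, a microRNA abundant in myeloid cells. Expression was measured on 12 arrays, 4 for the scramble control, 4 for the mimic pre-miR-223 and 4 for the inhibitor anti-miR-223, all 48 h after transfection. Values were log2 signals of 41345 transcript clusters, with medians between 2.21 and 2.31 per array, and 14611 genes were bright enough to be tested. The median 95% confidence interval of a difference between groups reached 0.29 on the log2 scale to either side.

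Replicate 4 of anti-miR-223 stood apart from the other 11 arrays. Its median correlation with them, across genes, was 0.967, against 0.988 to 0.992 for the others; genes are not independent replicates. In this array 629 genes (4.30%) lay over 2-fold from the 12-array mean, against at most 37 in any other. Small nucleolar RNAs, which guide the modification of ribosomal RNA, had a median of -1.41 relative to the 12-array mean, while protein-coding genes had a median of 0.10. Against the mean of the other 11 arrays, 817 genes lay over 2-fold away, 647 higher and 170 lower, and 73 of 74 small nucleolar RNA genes were lower. Ppp2ca, a phosphatase subunit, was lower by a log2 difference of -5.18, Rps18, a ribosomal protein gene, by -4.29, and Tuba1b, a tubulin gene, by -3.59. Elovl6, a fatty acid elongase, differed by 2.85, Idh3b, a subunit of isocitrate dehydrogenase, by 2.55, and Cat, the catalase gene, by 2.34. These genes were chosen after their values were seen.

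**Figure D1:**
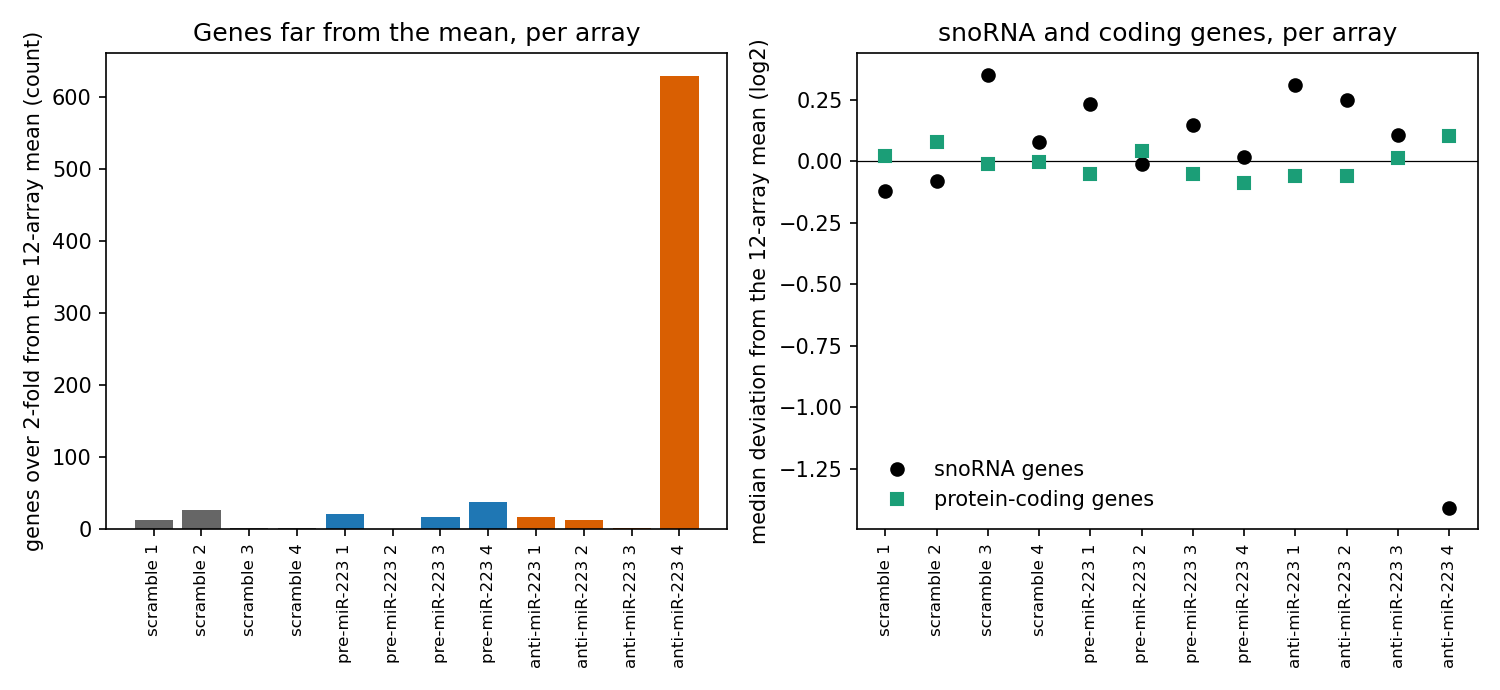
Left, the number of tested genes over 2-fold from the 12-array mean in each array, with bars from 0. Right, the median deviation (log2) from the 12-array mean of 74 small nucleolar RNA genes and of 13231 protein-coding genes in each array. Replicate 4 of anti-miR-223 has 629 such genes and a small nucleolar RNA median of -1.41.

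Pre-miR-223 was compared with scramble to see which genes follow added miR-223. Cd40, a co-stimulatory receptor of the TNF receptor family, had the smallest p: 2.43 ± 0.18 (SD, n = 4) with pre-miR-223 and 2.96 ± 0.14 with scramble, a difference of -0.53 (95% CI -0.77 to -0.29). Qpct, which encodes glutaminyl cyclase, differed by -0.48 (-0.70 to -0.25), Ackr3, an atypical chemokine receptor, by -0.49 (-0.73 to -0.24), Vsig10 by -0.47 (-0.70 to -0.23), and Dpm2, a subunit of dolichol-phosphate mannose synthase, by -0.41 (-0.61 to -0.21). The sterol reductase gene Tm7sf2 differed by -0.38 (-0.63 to -0.13) and the interferon-induced GTPase Mx2 by 0.37 (0.09 to 0.65). Tcirg1, a proton pump subunit of osteoclasts, differed by -0.22 (-0.52 to 0.07), or -0.11 without pre-miR-223 replicate 4. None of these differences passed the test over all genes. With pre-miR-223 and scramble, Ackr3 was at 2.32 and 2.80, Vsig10 at 2.46 and 2.93, and Mx2 at 2.71 and 2.34. These levels and those of Cd40 are close to the lowest level tested, so the size of the differences in these genes is uncertain. Cd40 passed when adjusted over the list alone, among the 22 tested genes of NF-kB inflammation (adjusted p = 0.00745); it was the only such call among the 24 lists and 3 comparisons. It passed on that list in 23 of 23 alternatives, with adjusted p between 0.00328 and 0.0471. These alternatives reuse the same arrays and are not independent support. The adjustment over a list alone takes no account of the 24 lists and 3 comparisons, so 1 such call can arise by chance. Over all genes Cd40 had an adjusted p of 0.921 by limma.

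Over all genes, limma called 0 of 14611 between pre-miR-223 and scramble, with a lowest adjusted p of 0.921. At an unadjusted p under 0.05 there were 711 genes, 149 higher and 562 lower, where chance gives 731; an ordinary linear model gave 0 calls and 706 such genes. The groups did not overlap for 435 genes (2.98%), against 2.86% by chance. The interval excluded a change of 1.5-fold or more in either direction for 82.8% of genes and of 2-fold or more for 98.5%. With each array centred on its median, the 577 genes at an unadjusted p under 0.05 were 315 higher and 262 lower. The 711 genes became 1371 without anti-miR-223 replicate 4, 1510 without pre-miR-223 replicate 2, 385 without scramble replicate 2, 455 without pre-miR-223 replicate 3 and 314 without pre-miR-223 replicate 4, with 0 calls in each case.

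No shared shift of reported miR-223 targets was detected with the mimic. Of the 29 tested, 10 were higher and 19 lower, with a mean of -0.04, which was 0.04 after centring or with level matching and 0.00 after a repeated quantile normalisation. The mean includes Mef2c at 1.09, the highest of the 29, in a cluster described below. The median of the list was -0.08, against -0.05 over all tested genes. The list mean was -0.02 without scramble replicate 2, pre-miR-223 replicate 3 or pre-miR-223 replicate 4. Camera gave an adjusted p of 0.892. Ccl3, a chemokine gene, had the smallest p, with a difference of -0.29 (95% CI -0.62 to 0.04), or -0.18 without pre-miR-223 replicate 4. The inflammasome gene Nlrp3 differed by -0.12 (-0.43 to 0.19), the transcription factor gene Nfia by -0.18 (-0.49 to 0.12), Stmn1, a microtubule destabiliser, by -0.13 (-0.42 to 0.15), and Rhob, a small GTPase, by 0.05 (-0.18 to 0.27). E2f1, a cell-cycle transcription factor, differed by -0.08 (-0.28 to 0.13) and Lmo2, a haematopoietic cofactor, by -0.02 (-0.27 to 0.24); both turned positive, to 0.00 and 0.06, after centring. Over fits without single arrays, Nlrp3 ranged from -0.20 to -0.04, Nfia from -0.29 to -0.07, Stmn1 from -0.18 to -0.09, Rhob from 0.00 to 0.13, E2f1 from -0.11 to -0.02 and Lmo2 from -0.07 to 0.09. The intervals excluded a fall of 2-fold or more for all 29 targets and of 1.5-fold or more for 25. These limits hold for the array signal, and the delivery of the mimic was not checked. Nfia, at 2.70 with pre-miR-223 and 2.88 with scramble, was close to the lowest level tested, where a fall may be understated.

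Mef2c, a transcription factor gene and a reported miR-223 target, had 2 clusters with different values. The brighter one (17294682) had 8.27 ± 0.55 (SD, n = 4) with pre-miR-223, 7.18 ± 1.07 with scramble and 7.08 ± 1.94 with anti-miR-223. Its difference was 1.09 (95% CI -0.53 to 2.71) for pre-miR-223 against scramble and -0.10 (-1.72 to 1.52) for anti-miR-223 against scramble. The former was 0.68 without scramble replicate 2. The latter turned positive without single arrays: 0.87 without anti-miR-223 replicate 4, 0.27 without scramble replicate 3 and 0.12 without scramble replicate 4. It lay between -0.51 and -0.27 without any 1 of the other 5 arrays. The other cluster (17288917) had -0.10 (-0.47 to 0.26) and 0.06 (-0.30 to 0.43) for these comparisons. Its intervals come from a fit of every cluster above the level filter, not of 1 cluster per gene. In that fit the brighter cluster had intervals of -0.69 to 2.86 and -1.87 to 1.68. Across the 12 arrays the clusters ran in opposite directions, with Pearson r = -0.938 (permutation p = 3e-05) and Spearman rho = -0.839 (permutation p = 0.001). The pair was tested after its disagreement had been seen, and the permutations treat the arrays as interchangeable. The arrays also differ along a first principal component with 48.8% of the variance. These p values therefore do not separate a property of Mef2c from differences between arrays. Another 64 pairs of same-gene clusters were correlated, without a test of each. Without the 2 arrays farthest from the median, anti-miR-223 replicate 4 and scramble replicate 2, r was -0.715.

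**Figure D2:**
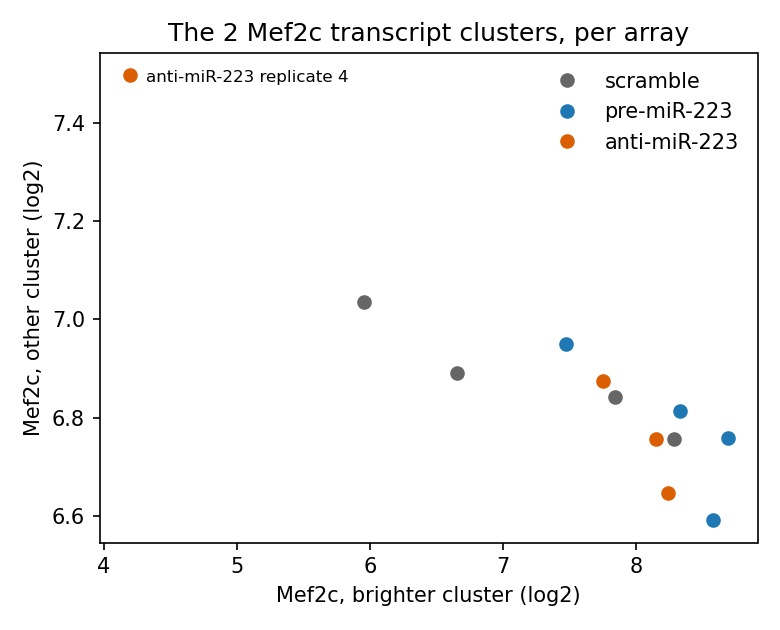
Log2 signal of the brighter Mef2c cluster (horizontal) and of the other Mef2c cluster (vertical) in each of the 12 arrays, coloured by group. The brighter cluster runs from 4.19 to 8.69 and the other from 7.50 down to 6.59; replicate 4 of anti-miR-223 is at the upper left.

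**Figure D3:**
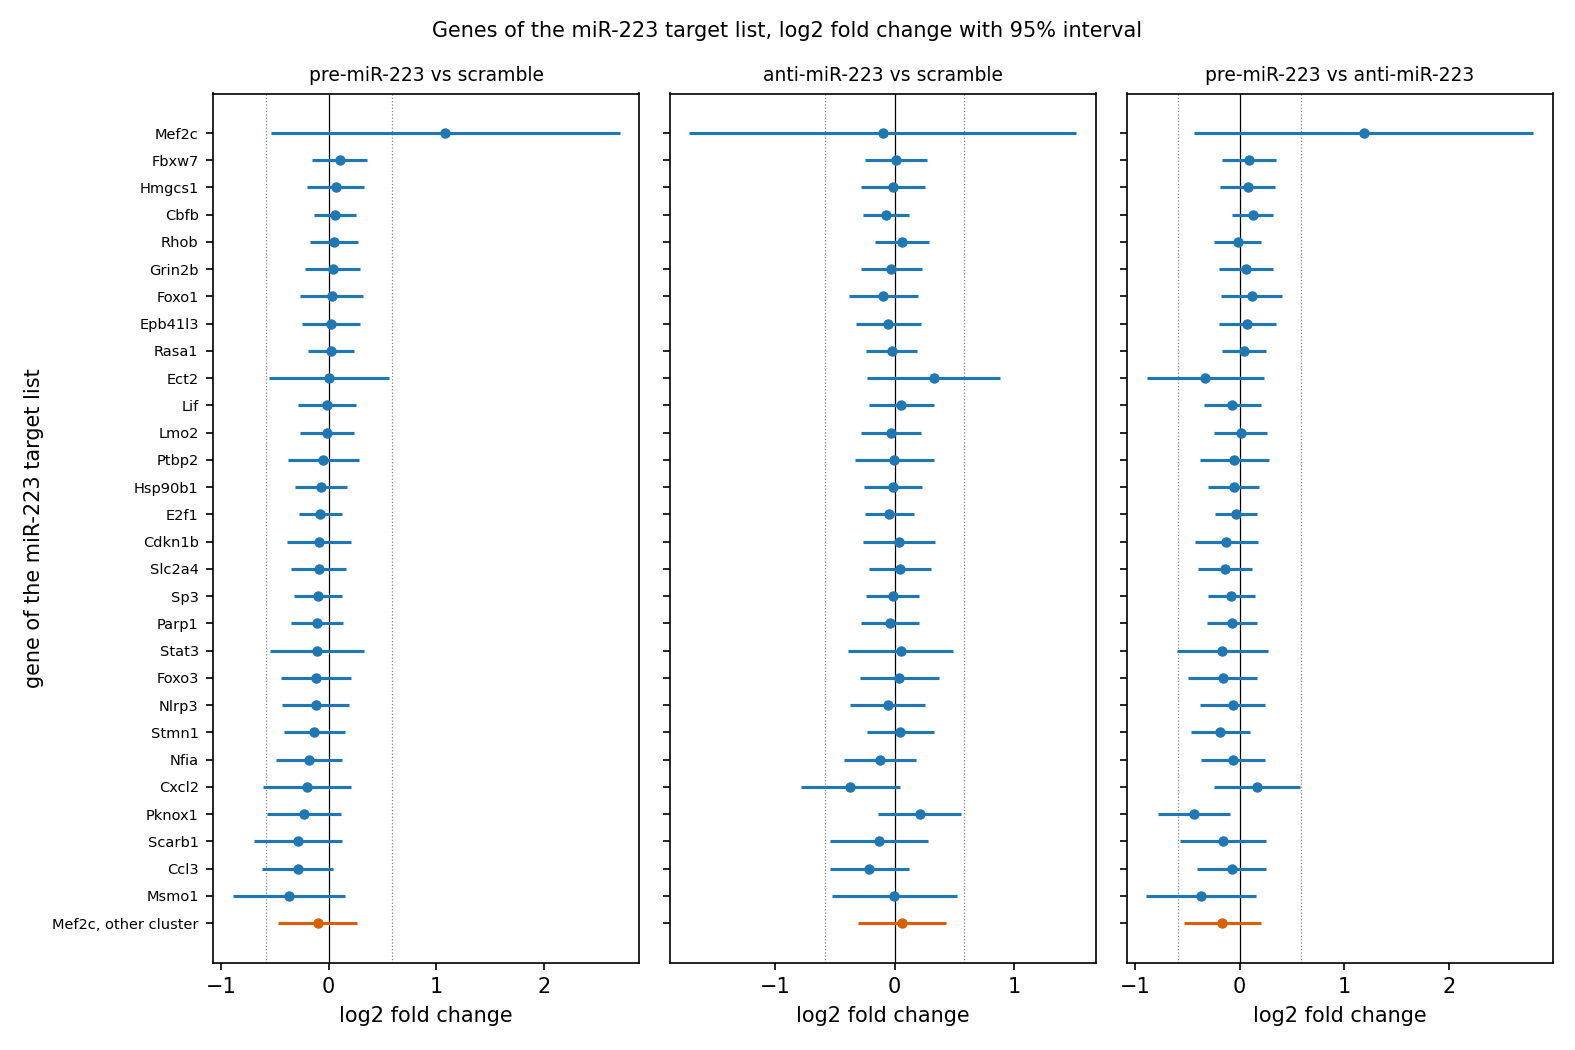
Log2 differences between groups with 95% confidence intervals (n = 4 arrays per group) for the 29 tested miR-223 targets, and for the other Mef2c cluster in orange; dotted lines mark a 1.5-fold change and each panel has its own horizontal scale. The intervals of the other Mef2c cluster come from a fit of every cluster above the level filter. The brighter Mef2c cluster has the widest interval, and no target passed the test in any of the 3 comparisons.

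Several gene groups were slightly lower with pre-miR-223 than with scramble, where the median difference over all tested genes was -0.05. On each of the 8 lower lists that passed camera below, pre-miR-223 replicate 2 lay above the 12-array mean. It did so by 0.02 for glycolysis and hypoxia up to 0.11 for macrophage identity. The other pre-miR-223 arrays lay below that mean on these lists. The chemokine list had a mean of -0.22, with 11 of 12 members lower: Ccl2 differed by -0.42 (95% CI -0.84 to 0.00) and Cxcl14 by -0.31 (-0.56 to -0.05), while Ccl6 differed by 0.09. Cholesterol synthesis had a mean of -0.20 (17 of 19 lower), including Srebf2, the transcription factor that drives the pathway, at -0.30 (-0.54 to -0.06). G1/S replication had -0.17 (24 of 26 lower), with Tk1, thymidine kinase, at -0.40 (-0.66 to -0.14), and NF-kB inflammation had -0.16 (20 of 22 lower). Macrophage identity had -0.15 (17 of 20 lower), with the lysosomal marker Cd68 at -0.34 (-0.63 to -0.05), and ribosomal proteins had -0.15 (20 of 21 lower). Glycolysis and hypoxia had -0.14 (16 of 17 lower) and lysosome -0.14 (17 of 18 lower). Fibroblast markers had a mean of 0.06, with 5 of 6 higher. These 9 lists of 24 passed camera with the preset correlation, at adjusted p between 0.00160 for ribosomal proteins and 0.0353 for fibroblast markers. None passed with an estimated correlation (lowest adjusted p = 0.660, for chemokines) or fry (lowest adjusted p = 0.223). With 1 array left out, none passed with an estimated correlation either, but chemokines and ribosomal proteins passed fry without pre-miR-223 replicate 2 (adjusted p = 0.0212 and 0.0318). The count of 9 was 5 without scramble replicate 2 and 4 without pre-miR-223 replicate 3. Chemokines, NF-kB inflammation, G1/S replication and ribosomal proteins passed with each of the 8 arrays left out in turn, and the other 5 lists lost their call without at least 1 array. The lysosome mean was -0.09 without scramble replicate 2, and that of fibroblast markers was 0.10 without scramble replicate 1 and 0.04 without pre-miR-223 replicate 4. The direction of each of the 9 held under every scaling tried, but the means shrank with cyclic loess. They were then -0.15 for chemokines, -0.10 for NF-kB inflammation, -0.09 for cholesterol synthesis, -0.06 for G1/S replication and ribosomal proteins, -0.05 for macrophage identity and for glycolysis and hypoxia, -0.03 for lysosome and 0.05 for fibroblast markers, which had 0.14 after centring. Genes of short span had a median of -0.10 ± 0.14 (SD, n = 4) with pre-miR-223 and 0.09 ± 0.05 with scramble, relative to the 12-array mean. That is a difference of -0.19 (exact permutation p = 0.0857), against -0.07 (p = 0.371) for genes of long span. Neither group of genes reached a p under 0.05, and short genes were not tested against long genes. The short genes ranged from -0.26 to -0.14 with 1 array left out, and the long genes from -0.11 to -0.02, the latter without scramble replicate 2.

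Anti-miR-223 was compared with scramble to see which genes follow a block of miR-223. C4b, a complement component gene, was at 2.52 ± 0.20 (SD, n = 4) with anti-miR-223 and 1.93 ± 0.19 with scramble, a difference of 0.60 (95% CI 0.32 to 0.87) close to the lowest level tested, log2 2.01. Epsti1, an interferon-induced gene, differed by -0.59 (-0.94 to -0.25), Ackr3 by -0.44 (-0.69 to -0.20), Csrp3, a muscle LIM protein gene, by -0.43 (-0.63 to -0.23), and Lyrm7, an assembly factor of respiratory complex III, by -0.36 (-0.57 to -0.15). The interferon-induced exonuclease gene Isg20 differed by -0.44 (-0.77 to -0.12), Nfkb2, an NF-kB subunit, by -0.27 (-0.52 to -0.01), the kinase gene Src by -0.23 (-0.44 to -0.03) and Mvk, mevalonate kinase, by 0.23 (-0.10 to 0.55), or 0.12 without anti-miR-223 replicate 3 and 0.36 without anti-miR-223 replicate 2. With anti-miR-223 and scramble, Ackr3 was at 2.36 and 2.80, Csrp3 at 2.23 and 2.66, and Lyrm7 at 2.60 and 2.96. These levels are also close to log2 2.01, so the size of their differences is uncertain. None of the genes in this paragraph passed the test. Limma called 0 of 14611 genes, with a lowest adjusted p of 0.988, and 294 had an unadjusted p under 0.05, 97 higher and 197 lower, where chance gives 731. An ordinary linear model gave 0 calls and 368 such genes. The groups did not overlap for 227 genes (1.55%, against 2.86% by chance), and the interval excluded changes of 2-fold or more for 98.9% of genes. Without anti-miR-223 replicate 4 the 294 genes became 978, with 0 calls.

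No shared shift of the miR-223 targets was detected with the inhibitor either. Of 29, 10 were higher and 19 lower, with a mean of -0.02 (adjusted p = 0.992 by camera); the mean was 0.00 with level matching or cyclic loess. Without anti-miR-223 replicate 4 it was -0.07 (24 of 29 lower, adjusted p = 0.269), and without scramble replicate 2 or anti-miR-223 replicate 1 or replicate 2 it was 0.01. Cxcl2, a neutrophil-attracting chemokine gene, had the smallest p among them, with a difference of -0.37 (95% CI -0.78 to 0.04). Nlrp3 differed by -0.06 (-0.37 to 0.25), Nfia by -0.12 (-0.43 to 0.18), Stmn1 by 0.05 (-0.23 to 0.33), Rhob by 0.06 (-0.16 to 0.29), E2f1 by -0.04 (-0.25 to 0.16) and Lmo2 by -0.03 (-0.28 to 0.22). Among fits without 1 array, Nlrp3 ranged from -0.15 to 0.04, Nfia from -0.21 to -0.06, Stmn1 from -0.07 to 0.17, Rhob from 0.03 to 0.15, E2f1 from -0.08 to 0.02 and Lmo2 from -0.09 to 0.08. Nlrp3 turned positive without anti-miR-223 replicate 1, Stmn1 negative without anti-miR-223 replicate 4 and E2f1 positive without scramble replicate 2. The intervals excluded a rise of 1.5-fold or more for 27 of the 29.

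Chemokines were lower with anti-miR-223 as well, with a mean of -0.18 and 11 of 12 members lower. Ccl2, the monocyte chemoattractant gene, differed by -0.57 (95% CI -0.99 to -0.15), Cxcl14 by -0.36 (-0.61 to -0.10) and Ccl6 by 0.16 (-0.13 to 0.45). Ribosomal proteins had a mean of -0.09 (19 of 21 lower), the interferon response -0.08 (20 of 28 lower) and G1/S replication -0.07 (20 of 26 lower). These 4 lists passed camera with the preset correlation, at adjusted p = 0.00306 for chemokines and 0.0415 for each of the others. With an estimated correlation none passed (lowest adjusted p = 0.384, for chemokines), and none passed fry (lowest adjusted p = 0.810), nor did any with 1 array left out (lowest adjusted p = 0.321 and 0.322). The count of 4 was 1 without scramble replicate 1 or without scramble replicate 2, and 2 without anti-miR-223 replicate 1, replicate 2 or replicate 3. Without anti-miR-223 replicate 4, ribosomal proteins had -0.04 and did not pass (adjusted p = 0.477), the interferon response had -0.18 and G1/S replication -0.16, and cholesterol synthesis passed with -0.17 (adjusted p = 0.00773). Without anti-miR-223 replicate 1 or replicate 2 the interferon response had -0.04 or -0.02 and G1/S replication -0.03 or -0.01. The interferon response had -0.14 without scramble replicate 4, and G1/S replication had -0.02 without scramble replicate 2. The direction of these 4 lists held under every scaling tried. The median of short genes differed by -0.07 (exact permutation p = 0.257) and that of long genes by 0.00 (p = 0.971). Without anti-miR-223 replicate 4 these were -0.08 and -0.13, and without anti-miR-223 replicate 2 they were -0.04 and 0.06.

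Level-matched chemokine scores separated scramble from both pre-miR-223 and anti-miR-223. The difference from scramble was -0.144 for pre-miR-223 and -0.152 for anti-miR-223, each with an exact permutation p of 0.0286, the smallest that 4 against 4 arrays can give. Adjusted over the 24 lists these were 0.392 and 0.686. With this smallest p, an adjusted p under 0.05 would need many lists to reach it together. Chemokines were the only list whose level-matched score had an exact p under 0.05 in either comparison, and both comparisons used the same 4 scramble arrays.

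**Figure D4:**
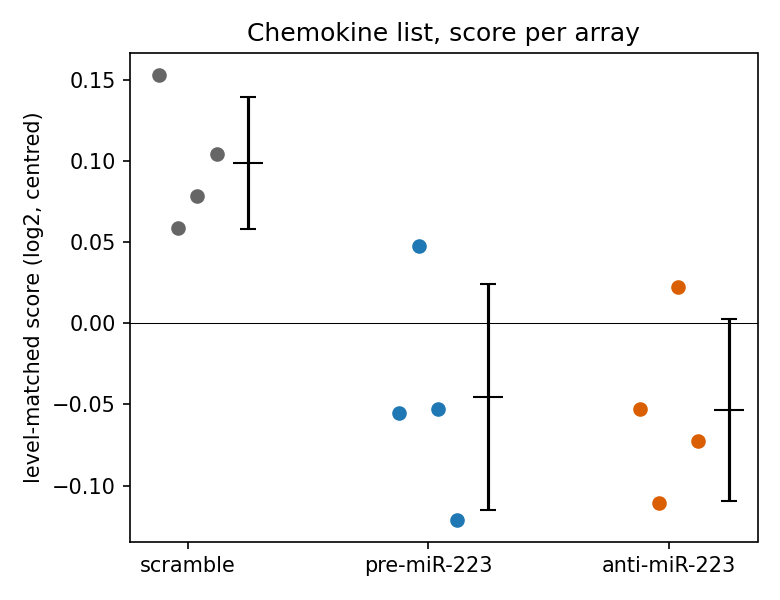
Level-matched score of the 12 tested chemokine genes in each array (log2, centred on the 12 arrays), with the mean and SD of each group (n = 4). The 4 scramble arrays lie between 0.06 and 0.15, and the other 8 lie between -0.12 and 0.05.

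Pre-miR-223 was compared with anti-miR-223 to set added against blocked miR-223 without the scramble mean. The scramble arrays still entered the estimate of the spread. C4b was at 1.83 ± 0.12 (SD, n = 4) with pre-miR-223 and 2.52 ± 0.20 with anti-miR-223, a difference of -0.69 (95% CI -0.96 to -0.42), the smallest p of this comparison. Krtap5-5, a keratin-associated protein gene, differed by -0.59 (-0.87 to -0.31), Usp17le, a deubiquitinase gene, by 0.68 (0.32 to 1.03), Isoc2a by 0.67 (0.30 to 1.04) and Dpm2 by -0.37 (-0.57 to -0.18). C4b with pre-miR-223 and Usp17le with anti-miR-223 (1.57 to 1.74 in its 4 arrays) lay below the lowest level tested, log2 2.01, so the size of these differences is uncertain. The same holds for genes close to that level. With pre-miR-223 and anti-miR-223, Krtap5-5 was at 2.28 and 2.87, Cd40 at 2.43 and 2.73, and Mx2 at 2.71 and 2.42. Cd40 differed by -0.30 (-0.54 to -0.06), Tm7sf2 by -0.37 (-0.62 to -0.12), Mx2 by 0.29 (0.01 to 0.57), or 0.18 without pre-miR-223 replicate 1, and Tcirg1 by -0.27 (-0.57 to 0.02), or -0.16 without pre-miR-223 replicate 4. None passed the test. Limma called 0 of 14611 genes, with a lowest adjusted p of 0.946; 528 genes had an unadjusted p under 0.05, 153 higher and 375 lower, and an ordinary linear model gave 0 calls and 530 such genes. After centring, the 538 such genes were 336 higher and 202 lower. The groups did not overlap for 244 genes (1.67%, against 2.86% by chance). The 528 genes became 1147 without pre-miR-223 replicate 2, 1014 without anti-miR-223 replicate 2 and 280 without pre-miR-223 replicate 4, with 0 calls each time. In a fit of only the 8 arrays of these groups they became 338, also with 0 calls.

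Among the miR-223 targets, Pknox1, a homeobox gene, differed by -0.44 (95% CI -0.78 to -0.09) between pre-miR-223 and anti-miR-223 and did not pass the test. Of 29 targets 10 were higher and 19 lower, with a mean of -0.02 (adjusted p = 0.998 by camera) that was 0.05 after centring and 0.02 without anti-miR-223 replicate 4. The median of the list was -0.06, against -0.04 over all tested genes, and the mean includes the brighter Mef2c cluster, the highest of the 29. The brighter Mef2c cluster differed by 1.18 (-0.44 to 2.80), or 0.22 without anti-miR-223 replicate 4. The other Mef2c cluster differed by -0.17 (-0.53 to 0.20) in the fit of every cluster. Stmn1 differed by -0.18 (-0.47 to 0.10), Nlrp3 by -0.06 (-0.38 to 0.25), Nfia by -0.06 (-0.37 to 0.24), Rhob by -0.02 (-0.24 to 0.21), E2f1 by -0.03 (-0.24 to 0.17) and Lmo2 by 0.01 (-0.24 to 0.27); Nlrp3, Nfia, Rhob and E2f1 turned positive after centring. Over the left-out arrays, Stmn1 ranged from -0.30 to -0.06, the latter without anti-miR-223 replicate 4, Nlrp3 from -0.17 to 0.03, Nfia from -0.17 to 0.05, Rhob from -0.06 to 0.02, E2f1 from -0.06 to 0.01 and Lmo2 from -0.03 to 0.05. The intervals excluded a fall of 1.5-fold or more for 25 of the 29 and of 2-fold or more for 29. No list passed camera; cholesterol synthesis had the lowest adjusted p, 0.0659, with a mean of -0.18 (17 of 19 lower). Without anti-miR-223 replicate 4 that mean was -0.02 (adjusted p = 0.970); the list passed without pre-miR-223 replicate 2 or anti-miR-223 replicate 1 or replicate 2, at adjusted p between 0.00468 and 0.0145 with the preset correlation. With an estimated correlation or fry no list passed, with all arrays or with 1 left out. Chemokines had a mean of -0.04 and a level-matched difference of 0.01. The count of 0 lists was 3 without pre-miR-223 replicate 2 and 1 without anti-miR-223 replicate 1, replicate 2 or replicate 4.

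The responses to pre-miR-223 and anti-miR-223, each against scramble, were correlated across genes with r = 0.370 (covariance 0.00816), and 0 genes were called in both. The jackknife SE of r over the 12 arrays was 0.415, larger than r itself. Genes are not independent replicates, and the 2 comparisons share the scramble arrays, so a positive correlation arises without any effect. Unchanged groups simulated with the same sharing gave a median r of 0.502 with independent noise and 0.580 with rotated array residuals (-0.289 to 0.901 over 100 draws). With the scramble arrays split so that none was shared, r lay between -0.230 and 0.198.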

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

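The split counts for unadjusted p, for the lists and for the residual component, the tests on transcript amount and on the inhibitor, and the level-matching test were chosen after the result was seen. The split counts for called genes, the scaling test and the other chemokine tests were set before their values were known. The gene span tests were too, but after the difference in short genes had been seen.

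Anti-miR-223 replicate 4 was far from the other 3 arrays of its group, with 629 genes over 2-fold from the 12-array mean against 1 to 17 in those arrays, a median correlation of 0.967 with the other arrays, and a small nucleolar RNA median of -1.41. After a repeated quantile normalisation 462 genes were still over 2-fold away, against at most 34 in any other array, which argues against scaling as the whole cause. Other clusters of 32 genes that moved in this array, with a level above 5, went the same way by a median of only 0.177 (95% CI -0.388 to 0.604). The first clusters had 1.26, and for 15 genes the other clusters went the opposite way. Clusters of the same symbol may measure different transcripts. The first clusters were also picked for a change over 2-fold, which the other clusters were not. This disagreement therefore cannot decide whether transcript amounts changed for these 32 genes. Their first clusters were lower for 25 and higher for 7. All 817 genes over 2-fold from the other 11 arrays were 647 higher and 170 lower, so these 32 do not represent them. On the 817 genes over 2-fold from the other 11 arrays, the other 3 inhibitor arrays differed from scramble by -0.221 in the direction of replicate 4, against 1.27 in replicate 4, which argues against an effect of the inhibitor. A difference in the RNA, its labelling or its hybridisation may stand behind this array; none of these was tested.

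With pre-miR-223, 8 of the 9 lists that passed camera with the preset correlation were lower than scramble; none of the 9 passed with an estimated correlation or fry on all arrays. Of the 35 splits of the 8 arrays, 3 gave at least 9 lists, the real one included, with up to 11 in another split, so chance cannot be excluded. Matching on level took away at least 50% of the mean shift for 6 of the 9 lists, which is consistent with a shift shared by genes of the same level; NF-kB inflammation kept 55.5% of its shift, chemokines 66.1% and fibroblast markers 78.5%. Matching on level and gene span together took away at least 50% for 7 of the 9, which is consistent with a shift that genes of the same level and span share; chemokines kept 61.1% and fibroblast markers 85.6%. An effect of the mimic on these groups stays open.

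The chemokine list lay below scramble with both pre-miR-223 and anti-miR-223, a pattern first noticed in the list tests on these same arrays. With the scramble arrays divided so that none was shared, both differences stayed below 0 in 6 of 6 assignments. Every scramble score lay above all 8 others, which fixes that outcome. Chance values of the shared scramble arrays and an effect of both pre-miR-223 and anti-miR-223 therefore cannot be told apart by this test. The 4 scramble arrays differed from the other 8 by 0.148 (exact permutation p = 0.00202; adjusted p = 0.0485 over 24 lists, the smallest that 495 splits can give). Under 17 alternatives the difference lay between 0.106 and 0.163. The adjusted p lay between 0.0485 and 0.267 and was under 0.05 in 3 of them. It was 0.097 with no filter and 0.0727 or more with any array left out. With an array left out, fewer splits keep the smallest adjusted p that a single list alone can reach above 0.05. Those settings could not pass, so their adjusted p values do not count against the difference. Chemokine genes have a short span, a median of 3.50 kb. With matching on level and gene span the difference was 0.130 (95% CI 0.0527 to 0.208, exact permutation p = 0.0242, not adjusted over the lists), so a part of gene span in it stays open. The scramble may have raised chemokine genes, or both oligonucleotides may have lowered them; the design has no untransfected cells, so this is a hypothesis only.

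For called genes, the real count by limma was 0 in each comparison, with up to 0, 0 and 5 calls in another split of pre-miR-223 and scramble, anti-miR-223 and scramble, and pre-miR-223 and anti-miR-223. At an unadjusted p under 0.05, in the same order, 4 splits gave as many as the real 711 genes (up to 1543 in another split), 31 as many as 294 (up to 2688) and 21 as many as 528 (up to 3219). For the lists, 9 splits gave as many as the real 4 of anti-miR-223 against scramble (up to 11), and another split gave up to 13 where pre-miR-223 against anti-miR-223 had 0. With the first residual component as a covariate, the real counts were 0, 0 and 97, with up to 813, 2039 and 2823 in another split, and 17 splits gave as many as the 97. Each of the 35 splits must give at least 0, so the splits decide nothing for the counts of 0. Chance can be excluded for none of the other counts, and splits with several times the real count point to a structure among the arrays other than the groups.

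Of 180 groups of 4 arrays examined, 13 had 1 array far from the rest, 7 of them replicate 4 of anti-miR-223; chance gives about 1 in 20, or 9. In that array Mef2c was at 4.19, against 7.75 to 8.24 in the rest of its group. Its level-matched scores were 0.339 for LXR-driven efflux and lipogenesis, 0.193 for p53 targets and 0.194 for PI3K, FOXO and IGF signalling, against scores below 0 in the other 3. Ackr3 was at 2.54 in anti-miR-223 replicate 1, against 2.27 to 2.31 in the others. Qpct was at 3.49 in scramble replicate 1, against 3.75 to 3.76. Rhob was at 3.23 in scramble replicate 2, against 2.87 to 2.91. Cxcl2 was at 4.07 in pre-miR-223 replicate 4, against 4.92 to 5.09. The fibroblast marker score was 0.0861 in pre-miR-223 replicate 4, against 0.0175 to 0.0265. Genes of middle level, log2 4 to 7, had a median deviation of 0.15 in scramble replicate 2, against 0.00 to 0.01 in the others.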

How the results depend on the processing

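Cyclic loess, residual components, median centring of the lists, level-matched scores, the other Mef2c cluster, the chemokine alternatives, left-out arrays for the shared response, and anti-miR-223 replicate 4 left out of pre-miR-223 against scramble were chosen after seeing the data; the others were planned. Of 151 values for the 3 gene counts, the 3 list counts and the shared response, 117 stayed within 1.5 times the main count or within its error, and 34 did not. The count of 0 genes held in each comparison under every filter, unit, scaling, variance model, array weighting and left-out array tried. It moved with residual components as covariates: for pre-miR-223 against scramble to 87 genes with 2 components and 203 with 3, and for pre-miR-223 against anti-miR-223 to 97 with the first, 211 with 2 and 316 with 3. Unadjusted p with a 1.5-fold change gave 41 genes for pre-miR-223 against scramble, 9 for anti-miR-223 against scramble and 30 for pre-miR-223 against anti-miR-223, a looser threshold by construction. List counts moved more. For pre-miR-223 against scramble, 9 became 4 above the 60th percentile, 5 after a repeated quantile normalisation, 3 with cyclic loess, 0 with an estimated correlation and 0 with level-matched scores, and 4 to 12 with 1 array left out. For anti-miR-223 against scramble, 4 became 2 after a repeated quantile normalisation, 2 with cyclic loess, 2 with the replicate block, 1 with trend and robust moderation, 0 with an estimated correlation and 0 with level-matched scores, and 1 to 4 with 1 array left out. For pre-miR-223 against anti-miR-223, 0 became 1 with no filter, 2 after centring, and 0 to 3 with 1 array left out. Of 314 values for single lists, 194 were the same, 100 lost their call and 20 changed direction without a call; fibroblast markers gave no value above the 60th percentile. Of 803 values for named genes, 762 kept their sign and 41, none of them called, did not. The shared response of 0.370 became -0.230, -0.061 and -0.020 when scramble 1 and 2, 2 and 4, or 2 and 3 served pre-miR-223 alone. The cause of these movements was not tested. The replicate number as a block left 0 genes called in each comparison. Residuals of arrays with the same number correlated between -0.503 and 0.393, which shows no steady pairing by number but does not exclude one. Signal over background limits the lists, with 41 genes too dim to test, and the 3 planned comparisons of seed-matched genes were not run.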

Other observations

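The tests of same-gene clusters were set after the Mef2c clusters had been seen to disagree, but before the test values were known.

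Other gene groups did not pass camera with the preset correlation between pre-miR-223 and scramble, though some had means as far below 0 as groups that passed. The NRF2 oxidative response had a mean log2 difference of -0.15, with 13 of 13 members lower. The interferon response also had -0.15, with 22 of 28 lower, including Irf7, a regulator of interferon genes, at -0.52 (95% CI -0.92 to -0.13), while Mx2, the member with the smallest p, went the other way at 0.37. LXR-driven efflux and lipogenesis had -0.13, p53 targets -0.12, G2/M mitosis -0.12 and osteoclast genes -0.10. PI3K, FOXO and IGF signalling had -0.08, the microRNA machinery -0.06, the unfolded protein and integrated stress response -0.05 and alternative activation -0.01. Each of these last 4 means turned positive under at least 1 scaling, median centring or cyclic loess. Among markers of other cell types, neutrophil or dendritic genes had -0.06 and lymphoid genes -0.02, both positive after centring, and epithelial genes had 0.06. Left-out arrays moved these means: without scramble replicate 2, G2/M mitosis had -0.07, osteoclast genes -0.06, PI3K, FOXO and IGF signalling -0.04, the microRNA machinery -0.02, the unfolded protein and integrated stress response -0.02 and alternative activation 0.01. Without pre-miR-223 replicate 2 the same groups had -0.18, -0.13, -0.13, -0.12, -0.09 and -0.04. Without pre-miR-223 replicate 4 the interferon response had -0.09 and the unfolded protein and integrated stress response -0.01. Neutrophil or dendritic genes ranged from -0.10 to -0.02, lymphoid genes from -0.06 to 0.02 and epithelial genes from 0.04 to 0.09. With 1 array left out, the interferon response passed without scramble replicate 4, pre-miR-223 replicate 1 or pre-miR-223 replicate 2 (adjusted p between 0.00848 and 0.0292). G2/M mitosis passed without scramble replicate 1 or pre-miR-223 replicate 2 (0.0471 and 0.0320), and the NRF2 oxidative response without anti-miR-223 replicate 4 (0.0424). None of these 3 passed with an estimated correlation or fry in these settings.

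Between anti-miR-223 and scramble, the unfolded protein and integrated stress response had a mean of 0.07 (12 of 20 higher). NF-kB inflammation had -0.04, osteoclast genes -0.03 and cholesterol synthesis -0.01, which turned positive after a repeated quantile normalisation. None of these 4 passed camera. With 1 array left out the means ran from -0.03 to 0.14, -0.13 to 0.01, -0.12 to 0.03 and -0.17 to 0.07, in the same order, lowest without anti-miR-223 replicate 4 and highest without anti-miR-223 replicate 2. Without replicate 4 cholesterol synthesis passed (adjusted p = 0.00773). Without anti-miR-223 replicate 2 the unfolded protein and integrated stress response passed, with a mean of 0.14 (adjusted p = 0.0302). These calls used the preset correlation; no list passed with an estimated correlation or fry in this comparison, with all arrays or with 1 left out.

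Opposite movement of the Mef2c clusters was compared with other genes that had more than 1 cluster. Among 64 pairs of same-gene clusters, from 35 genes with a mean level above 5 and an SD above 0.3, the median r was 0.638 and 23.4% of pairs had r under -0.5. Pairs drawn from different genes gave 12.5% to 46.9% over 1000 draws, so opposite movement was no more frequent within genes than between them. Without anti-miR-223 replicate 4 the Mef2c clusters kept r = -0.821, which argues against 1 array as the source. The Mef2c pair was not among these 64 pairs, because its other cluster did not reach that SD. Across the arrays the brighter cluster tended to be dimmer where the first principal component, 48.8% of the variance, was higher. That component was 54.2 in anti-miR-223 replicate 4, 17.4 in scramble replicate 2 and -18.3 in pre-miR-223 replicate 4. Those arrays had brighter-cluster signals of 4.19, 5.95 and 8.58. Whether this array-wide difference, different transcripts or another sequence accounts for the opposite movement was not separated by any test here.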
